A study of Sus scrofa with 20 samples.

How the data were processed

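Total RNA from the longissimus muscle of 20 female pigs, 10 with low and 10 with high residual feed intake (RFI), was reverse transcribed, labelled with biotin and hybridised to Affymetrix Snowball arrays with 1 colour, per the labels' protocols. Each array is treated as 1 animal, because the design text gives 10 female pigs per group and each array carries its own label number; the labels give no litter, age or batch. The group of each array was taken from its RFI label, and replicates were numbered within a group for naming only.

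The values analysed are the log2 signals per probe set that the authors deposited for all 20 arrays, and the log2 scale itself was read from their range. GCOS 1.1.1 is named in the submitters' processing notes; how probes were summarised, corrected for background and normalized is not given in the sources used here. The array means lay between 3.33 and 3.35, so the deposited values were taken as normalized between arrays and tested as they stood. Log2 signals of dim probe sets are compressed towards the background, so differences of genes with a low signal understate or blur the true ratio. The number of arrays limits the precision.

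The table held 47845 probe sets, of which 123 were controls and were left out of the tests. Probe sets with a mean over the 20 arrays above the 30th percentile of the non-control probe sets (1.75) were kept, which left 33405. Gene names came from the array's platform annotation: 26426 probe sets had 1 symbol, 0 had several and 21419 had none here. For 428 probe sets an outdated symbol was updated through a synonym, and of the 12209 genes represented 12159 were found in the reference gene tables. A gene was represented by its probe set of highest mean, and 4933 genes had more than 1 tested probe set. The brightest probe set of 136 genes was named after a microRNA, 1 of them in a list (PSMB5), and such a value does not measure the transcript of a host gene. Genomic positions were not analysed here.

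Groups were compared with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Gene lists were tested with limma's camera, with the correlation between genes estimated for each list, and adjusted over the 42 lists with at least 5 measured genes. Beside it stood camera with a preset correlation of 0.01, fry, and a permutation test (100000 resamples) of the difference of the mean list score between groups; intervals of mean scores are 95% confidence intervals. The data points were drawn with matplotlib 3.10.9 in Python 3.11.15. The analysis was tested on simulated data made from 20 random splits of these arrays, with 1000 probe sets shifted by each amount over the splits. There limma recovered 37.9% of shifts of 0.5, 88.8% of shifts of 1, 97.6% of shifts of 1.5 and 99.9% of shifts of 2, and called 181 of 664100 unshifted probe sets. All amounts were shifted together in each split, which eases the adjusted threshold. The shifts were also added in full to dim probe sets. These shares therefore overstate the recovery where few probe sets differ or signals are compressed. With the collagen list shifted by 0.3, camera called it in 18 of 20 splits with an estimated correlation and in 20 with the preset, and called 0 and 96 of 820 other lists. That shift was larger than any list difference reported below, the largest being 0.19. Other lists, such as fibroblast and tendon, were shifted only in the genes they share with the collagen list. Calls of other lists were therefore not all false by design. The simulation does not show the power for the list differences reported below.

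The genes named in the text follow a rule set before the data were examined, as were the gene lists and the main tests. Named were the 12 genes higher and the 12 lower in low RFI with the smallest p, filled up by unadjusted p where fewer passed, up to 4 members of each list by p, and up to 5 genes in each direction with an absolute difference of at least 1 and an unadjusted p under 0.05. Of the represented genes, 11763 had a symbol eligible for naming. The 31 function lists covered respiratory chain complex I, complexes II to V, TCA cycle, fatty acid uptake and oxidation, fat and sterol synthesis, glycolysis and glycogen, insulin signalling, growth axis and mTOR, proteasome and atrophy, autophagy, cytosolic and mitochondrial ribosomes, translation, slow and fast fibre genes, sarcomere, calcium handling, myogenic genes, heat shock, unfolded protein response, antioxidant genes, hypoxia, immediate early genes, circadian clock, interferon response, antigen presentation, inflammation, collagen and matrix, creatine and amino acid metabolism, mitochondrial dynamics, and feed efficiency candidates. The 11 cell type lists held markers of adipocytes, fibroblasts and tendon, endothelium, smooth muscle, macrophages, T and NK cells, B and plasma cells, neutrophils and mast cells, red blood cells, nerve, and satellite cells. Of 1170 distinct list genes 931 were measured.

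The alternatives planned were no filter, a filter at the median, quantile normalization, median centring, an intensity trend with a robust prior, array weights, leaving out each animal in turn, a block for label numbers 1 to 10 against 11 to 20, covariates for the first residual principal component and for the adipocyte score, a rank test, a test against a difference of 0.2, other thresholds, other ways to combine probe sets, and lists of at least 10 genes. Added after the data were examined were the mean signal of the 23 background control probe sets as a covariate, cyclic loess normalization, leaving out the 4 arrays of highest background control signal, and a filter at a mean of 5.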

Results

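Gene expression was measured in the longissimus muscle, the long muscle of the back, of 20 female pigs, with 1 single-colour Affymetrix Snowball array per animal. The animals differed in residual feed intake (RFI), the feed an animal eats beyond what its growth and maintenance are predicted to need, so that a low value means a more feed-efficient pig. There were 10 animals with low RFI and 10 with high RFI. The medians of the deposited log2 values per array lay between 2.79 and 2.89. Between-array correlations over the tested probe sets ranged from 0.916 to 0.978. The number of arrays limits the precision. The single comparison of the design asked which transcripts of muscle differ between feed-efficient and less efficient animals. All differences below are low RFI minus high RFI on the log2 scale, with 10 animals per group.

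None of the genes with the smallest p-values passed the threshold. CYP11A1, the side-chain cleavage enzyme that opens steroid hormone synthesis, had a signal of 3.17 ± 0.64 (SD, n = 10) in low RFI and 1.70 ± 0.92 (SD, n = 10) in high RFI, a difference of 1.46 ± 0.32 (SE). The mean of both its probe sets differed by 0.73, so the brighter probe set carried nearly all of the difference. LIPM, a member of the acid lipase family, lay at 1.26 ± 0.44 in low RFI and 2.33 ± 0.60 in high RFI, a difference of -1.08 ± 0.22. The group means of both genes lay below the mean background control signal of 3.65, so the size of these differences is uncertain. AURKA, a mitotic kinase, was 0.64 ± 0.14 higher in low RFI, CXCR6, a chemokine receptor of T cells, 0.74 ± 0.19 higher, and TK2, the thymidine kinase of mitochondria, 0.84 ± 0.24 higher.

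TFAM, which packages and transcribes mitochondrial DNA, differed by -0.40 ± 0.12. PLIN5, a lipid droplet protein of oxidative tissue, differed by -0.31 ± 0.10, and PEX11A, which takes part in peroxisome division, by -0.31 ± 0.10. CRK, an adaptor of signalling complexes, differed by -0.60 ± 0.18 and HIPK2, a nuclear kinase, by -0.35 ± 0.12, with all 6 of its probe sets on the same side. The other genes of smallest p lower in low RFI were DFNB59 at -0.63, NFAM1 at -0.52, DYTN at -0.44, NDP at -0.40, CBFA2T3 at -0.31 and CCNB1IP1 at -0.29. Higher in low RFI were LIMK2 by 0.48, OTUD7A by 0.47, LYZL6 by 0.47, TRIP11 by 0.43, DAPP1 by 0.42, SERTAD2 by 0.41, LYSMD4 by 0.38 and GANAB by 0.32. SERTAD2 rested on 1 of its 3 probe sets and TRIP11 on 1 of 2, since the others went the opposite way. Probe sets of the same gene also disagreed in sign for GANAB, ACACA, FDFT1, FH, HK1, PPARA, PDK4, CAMK2B, EYA1, MYH4, CASP9, NR3C1, SLC7A8, CHI3L1, TLR4, CD4, HBB, PPARG and PCK1, so the values given for these genes belong to their brightest probe set. Only 3 genes combined a difference of at least 1 with an unadjusted p under 0.05, namely CYP11A1, LIPM and LRCH2, which differed by -1.23 ± 0.51. Both group means lay below the mean background control signal of 3.65 for PLIN5, PEX11A, DFNB59, NFAM1, DYTN, NDP and CCNB1IP1. So did those of OTUD7A, TRIP11, DAPP1 and LRCH2, and the size of all these differences is uncertain.

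Across 33405 probe sets, limma called 0 as different at a Benjamini-Hochberg adjusted p under 0.05. The smallest adjusted p was 0.941, from limma, and a rank test on the same values also called 0. At an unadjusted p under 0.05 limma counted 1306 probe sets, 828 higher and 478 lower in low RFI, where 1670 would be expected by chance. The lowest p of a named gene in this ranking was 5.63e-05 for LIPM, with an adjusted p of 0.941 in limma, and CYP11A1 followed with p = 1.64e-04 and an adjusted p of 0.998. The CYP11A1 value turned on 1 animal: high RFI replicate 9 read 4.15 where the next highest animal of its group read 2.14, and without it the difference was 1.74 with a limma adjusted p of 0.00364. The median half-width of the 95% confidence interval was 0.26, and for 97.3% of the probe sets the interval excluded a 2-fold difference of the signal. Only 55.4% of the tested probe sets had a mean above the mean background control signal of 3.65, and of these 97.1% had such an interval. For the dimmer ones a narrow interval does not exclude a 2-fold difference of the transcript. Nor does it for probe sets above 3.65 that lie near the background of their own probe composition, where control means ran from 1.03 to 7.84.

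**Figure D1:**
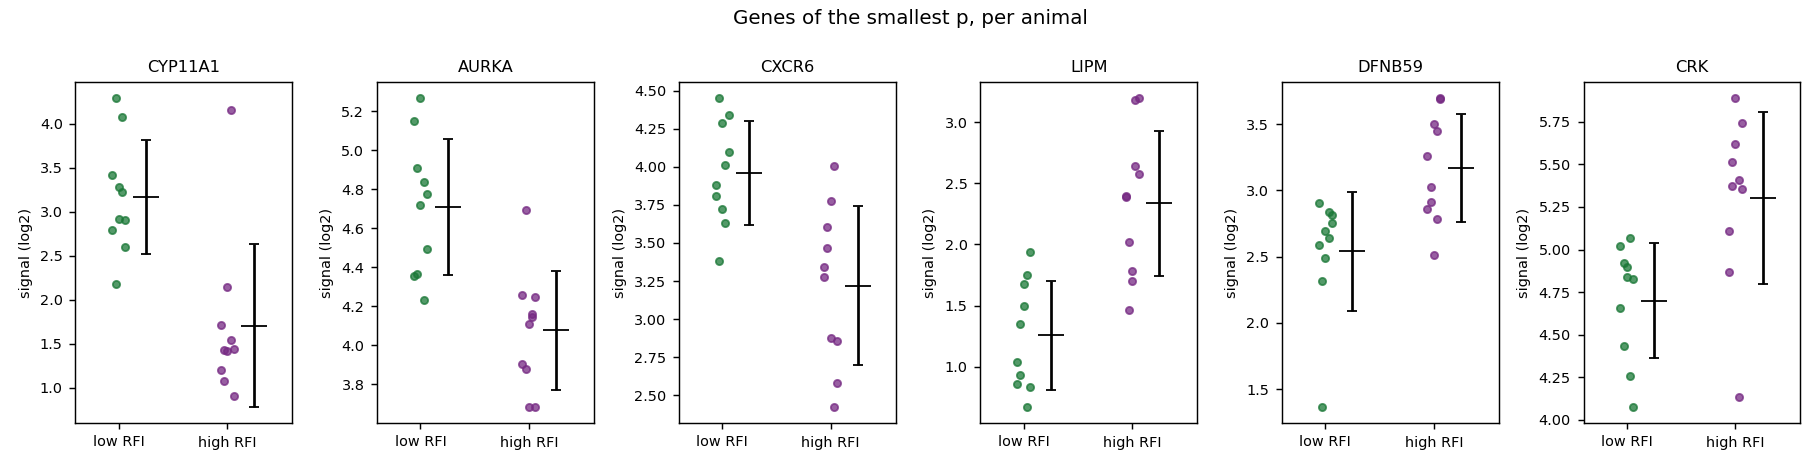
Log2 signal (vertical axis) of the 3 genes of smallest p higher in low RFI (CYP11A1, AURKA, CXCR6) and the 3 lower (LIPM, DFNB59, CRK), with 1 point per animal and the mean ± SD of each group of 10 beside it. In CYP11A1 all high RFI animals but the one at 4.15 lie at or below 2.14, under the lowest low RFI animal at 2.18.

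For fuel metabolism, members of the oxidative lists mostly had lower values in low RFI, by small amounts that camera with an estimated correlation did not call. In the list of fatty acid uptake and oxidation 24 of 29 measured genes were lower, and the mean score differed by -0.17 (95% interval -0.38 to 0.052). Its member of smallest p was PLIN5, with both group means below the mean background control signal. Then came PPARA, the fatty acid receptor that drives oxidative genes, at -0.30. PDK4, which holds pyruvate out of the mitochondrion's oxidation, stood at -0.68 and ETFDH at -0.30. The TCA cycle list differed by -0.16 with 13 of 15 genes lower, including DLD at -0.47, SUCLG2 at -0.35, PDHA1 at -0.27 and FH at -0.22. Respiratory chain complex I differed by -0.10 with 24 of 26 genes lower (NDUFB1 -0.25, NDUFA8 -0.20), and complexes II to V by -0.072 with 19 of 25 lower (UQCRB -0.35, COX7C -0.21). In limma's camera with an estimated correlation these 4 lists had adjusted p-values of 0.367, 0.805, 0.805 and 0.805. The scores of fatty acid oxidation (r = -0.903) and the TCA cycle (r = -0.965) ran against the arrays' main axis of variation, which followed background control signal. With that signal as a covariate, added after the data were examined, the differences shrank to -0.10 ± 0.065 (SE) for fatty acid oxidation, -0.063 ± 0.065 for the TCA cycle and -0.051 ± 0.063 for complex I.

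Glycolysis and glycogen genes differed by -0.067 (14 of 24 lower; PHKG1 -0.20, HK1 0.22). The list of insulin signalling and glucose uptake differed by -0.10 (19 of 25 lower; -0.042 with the background covariate; SOCS3 -0.46, TBC1D4 -0.27). Fat and sterol synthesis genes were 0.079 higher in low RFI (12 of 21 higher), with ACACA, the cytosolic acetyl-CoA carboxylase, at 0.77 ± 0.26 and FDFT1 at -0.36 ± 0.18. The list of mitochondrial dynamics, uncoupling and thermogenesis differed by -0.040 (19 of 31 lower), with UCP2, an inner membrane carrier, at 0.35 ± 0.15 against TFAM at -0.40. Creatine, amino acid and nucleotide metabolism differed by -0.035 (25 of 41 lower; SLC7A8 -0.35, BCAT2 -0.21). Without the 4 arrays of highest background the glycolysis, mitochondrial dynamics and creatine lists turned to 0.013, 0.0063 and 0.0015. For these lists limma's camera gave an adjusted p of 0.805 with an estimated correlation.

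Lists of the contractile apparatus were not called by camera with an estimated correlation either. All 12 measured slow fibre genes were lower in low RFI, with a mean difference of -0.15 (95% interval -0.58 to 0.29; -0.070 with the background covariate), and among them MYOZ2 differed by -0.43, PLN by -0.41, MYL3 by -0.12 and MYH7, the slow myosin heavy chain, by -0.090. These genes varied together between animals, with an estimated correlation of 0.692, and the adjusted p in limma's camera was 0.805. Fast fibre genes differed by -0.0022 (11 of 16 lower), a sign that turned under cyclic loess normalization, array weights, the label block, the adipocyte and background covariates and without the 4 arrays of highest background, with MYH4 at -0.063 and EYA1 at 0.20. Sarcomere and Z disc genes differed by -0.12 (22 of 26 lower; -0.020 with the background covariate; LMOD3 -0.70, XIRP2 -0.39), and calcium handling genes by -0.098 (19 of 22 lower; CAMK2B -0.23, SRL -0.15), the last shrinking to -0.034 with the background covariate. Myogenic and developmental muscle genes stood at 0.00064 (11 of 20 higher; CHRNG 0.28, CHRND 0.23) and the satellite cell markers at 0.0049 (4 of 8 higher; VCAM1 0.17), both below 0 once arrays were centred on their medians. Adjusted p-values from limma's camera were 0.939 for fast fibre genes, 0.805 for sarcomere and for calcium handling genes, 0.831 for myogenic genes and 0.999 for satellite cells.

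Protein turnover and growth lists gave a similar picture of small differences. In the ubiquitin, proteasome and atrophy list 28 of 33 genes were lower, with a mean difference of -0.11 that shrank to -0.033 with the background covariate. Its member PSMB5 was read from a mouse microRNA probe set that carries the symbol, and without it 27 of 32 genes were lower, with a mean difference of -0.11. FBXO32, the muscle ubiquitin ligase atrogin-1, differed by -0.37 ± 0.21 and UBE2D1 by -0.31 ± 0.17. The autophagy, calpain and lysosome list had a mean of 0.0016 but a median of -0.051, and camera placed it lower, as did centring the arrays on their medians. CASP9 was 0.31 ± 0.10 higher and ULK1 stood at -0.18. Cytosolic ribosomal proteins differed by -0.012 (25 of 43 lower, above 0 under cyclic loess normalization). Mitochondrial ribosomal proteins differed by -0.064 (27 of 39 lower, MRPS30 -0.40), and by -0.015 with the background covariate. Translation factors differed by -0.050 (21 of 30 lower, EIF4A2 -0.29). Their difference was 0.014 with the background covariate and 0.022 without the 4 arrays of highest background. The growth axis and mTOR list differed by -0.051 (17 of 29 lower), and by -0.0088 with the background covariate. Among its members MSTN, the brake on muscle growth known as myostatin, differed by -0.43 ± 0.19. GHR, the growth hormone receptor, differed by -0.38 ± 0.25 and SESN3 by 0.24 ± 0.11. Candidates for feed efficiency named in livestock work stood at -0.037 (16 of 31 lower; 0.0037 without the 4 arrays of highest background), with UCP2, MSTN, GHR and the glucocorticoid receptor NR3C1 (-0.44) as the members of smallest p. Limma's camera gave adjusted p-values of 0.939 for the autophagy list, 0.973 for cytosolic ribosomes and 0.805 for the other 5 lists with an estimated correlation.

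Connective tissue and macrophage genes had higher values in low RFI, though no list passed the test. In the fibroblast and tendon list 12 of 13 markers were higher, with a mean score of 6.76 ± 0.10 (SD, n = 10) in low RFI and 6.62 ± 0.13 (SD, n = 10) in high RFI, a difference of 0.14 (95% interval 0.033 to 0.25). COL3A1, the fibrillar collagen III chain, was 0.21 ± 0.11 higher, KERA 0.26 ± 0.15, FMOD 0.24 ± 0.14 and MFAP5 0.22 ± 0.14. The collagen and extracellular matrix list was 0.11 higher (95% interval -0.016 to 0.23), with 46 of 56 genes higher and 7 members at an unadjusted p under 0.05, among them LOXL2, a collagen cross-linking enzyme, at 0.29 ± 0.10, FBN1 at 0.31 ± 0.12, FBLN5 at 0.23 ± 0.090 and COL5A2 at 0.23 ± 0.10. As drawn up, this list shares COL1A1, COL3A1, DCN, LUM, THBS4 and FMOD with the fibroblast and tendon list, so their results are not independent. Macrophage and monocyte markers were 0.19 higher (95% interval 0.018 to 0.36; 12 of 14 higher), falling to 0.11 among genes with a mean of at least 5, with LYZ at 0.51 ± 0.18, the scavenger receptor MSR1 at 0.48 ± 0.21, VSIG4 at 0.46 ± 0.19 and TYROBP at 0.26 ± 0.12. The LYZ means, 2.33 in low RFI and 1.82 in high RFI, lay below the mean background control signal. The unadjusted camera p-values from limma were 0.00601, 0.0425 and 0.0437 and the adjusted p-values 0.252, 0.367 and 0.367. The permutation p-values of the mean scores, 2-sided, were 0.0148, 0.0855 and 0.0331, with adjusted values of 0.623, 0.790 and 0.695. Leaving out high RFI replicate 10 took the fibroblast and tendon list past the threshold, with a difference of 0.17 and a limma camera adjusted p of 0.0380.

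Markers of the other cell types differed little. Endothelial markers were 0.041 higher (9 of 15; LYVE1, of lymphatic vessels and some macrophages, 0.66 ± 0.23, but KDR -0.25), nerve and Schwann cell markers 0.035 higher (8 of 11; S100B 0.30, PRX -0.28, MAL -0.32). B and plasma cell markers were 0.047 higher (4 of 7; CD79A 0.27). Adipocyte markers had a mean difference of 0.023 (95% interval -0.25 to 0.30; 9 of 16 higher), with ADIPOQ, the adipocyte hormone adiponectin, at 0.45 ± 0.42, PPARG at 0.23 and PCK1 at -0.42. Smooth muscle and pericyte markers stood at 0.00048 (7 of 10 higher; RGS5 -0.32) and T and NK cell markers at -0.0030 (9 of 15 lower; CD4 -0.26). Neutrophil and mast cell markers stood at 0.012 (4 of 8 higher; S100A9 -0.15) and red blood cell markers at 0.0016 (3 of 6 higher; SLC4A1 0.19, HBB -0.20). Median centring took the smooth muscle and red blood cell values below 0, and cyclic loess normalization the neutrophil and red blood cell values. Without the 4 arrays of highest background B and plasma cell markers turned to -0.016 and T and NK cell markers to 0.0083. Adjusted p-values in limma's camera were 0.831 for endothelial cells, 0.973 for adipocytes, 0.933 for neutrophils and mast cells, and 0.805 for the other 5 lists. Direction was not settled in lists so close to 0: for adipocyte, neutrophil and satellite cell markers the mean was above 0 while camera placed the list lower, and for red blood cell markers the median of -0.029 opposed the mean and the test.

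Immune, stress and clock genes were the remaining groups. Interferon response genes differed by -0.078 (21 of 33 lower), a direction that turned to 0.012 among genes with a mean of at least 5, with DDX58, the RNA sensor RIG-I, at -0.48 ± 0.28, IFIT1 at -0.34 and IFIT3 at -0.29. Antigen presentation genes were 0.066 higher in low RFI (18 of 23; SLA-8 0.27, CTSS 0.30). Inflammation and acute phase genes were 0.038 higher (23 of 38; -0.0081 at a mean of at least 5), with complement C3 at 0.60 ± 0.24, CHI3L1 at 0.36 ± 0.16, TLR4 at 0.34 ± 0.16 and RELB at 0.26 ± 0.12. Circadian clock genes differed by -0.12 (95% interval -0.29 to 0.039; 13 of 15 lower; -0.077 with the background covariate), with RORA at -0.44, DBP at -0.22 and PER1 at -0.14. Heat shock and protein folding genes differed by -0.089 (20 of 27 lower; -0.0066 with the background covariate; DNAJA1 -0.47, HSP90AA1 -0.37). Immediate early and glucocorticoid response genes differed by -0.059 (22 of 38 lower; CTGF 0.23), and hypoxia genes by -0.059 (13 of 17 lower; 0.017 with the background covariate and 0.021 without the 4 arrays of highest background; HIF1A -0.36). Genes of the unfolded protein and integrated stress response were 0.062 higher (13 of 22; -0.026 at a mean of at least 5; PSAT1 0.67 ± 0.34, TRIB3 0.24 ± 0.12), and antioxidant genes were 0.013 higher (17 of 31; -0.0087 at a mean of at least 5; GSR 0.42 ± 0.18). Limma's camera gave adjusted p-values of 0.713 for the interferon list, 0.367 for the circadian list, 0.848 for antioxidant genes and 0.805 for the other 6.

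Over the 42 lists, limma's camera with an estimated correlation called 0 at an adjusted p under 0.05, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.252. The self-contained test fry, which asks whether a list's genes move on balance in a single direction, called 0 as well (smallest adjusted p 0.344), and so did the permutation of mean scores (smallest adjusted p 0.623). Of the 931 list genes measured, 0 passed when adjusted over the list alone and 0 when adjusted over all probe sets. With a preset correlation of 0.01 camera called 10 lists, and none of these calls held with an estimated correlation. Single animals moved this count: it was 4 without low RFI replicate 9, 6 without high RFI replicate 5 or 10, and 16 without low RFI replicate 5 or high RFI replicate 9. At a mean of at least 5 it was 7, without macrophage and monocyte. The 3 higher in low RFI were collagen and extracellular matrix (adjusted p = 0.367 with an estimated correlation), fibroblast and tendon (adjusted p = 0.252 with an estimated correlation) and macrophage and monocyte (adjusted p = 0.367 with an estimated correlation). The 7 lower were fatty acid uptake and oxidation and circadian clock (both adjusted p = 0.367 with an estimated correlation), interferon response (adjusted p = 0.713 with an estimated correlation, and above 0 among genes with a mean of at least 5), and respiratory chain complex I, TCA cycle, proteasome and calcium handling (each adjusted p = 0.805 with an estimated correlation).

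**Figure D2:**
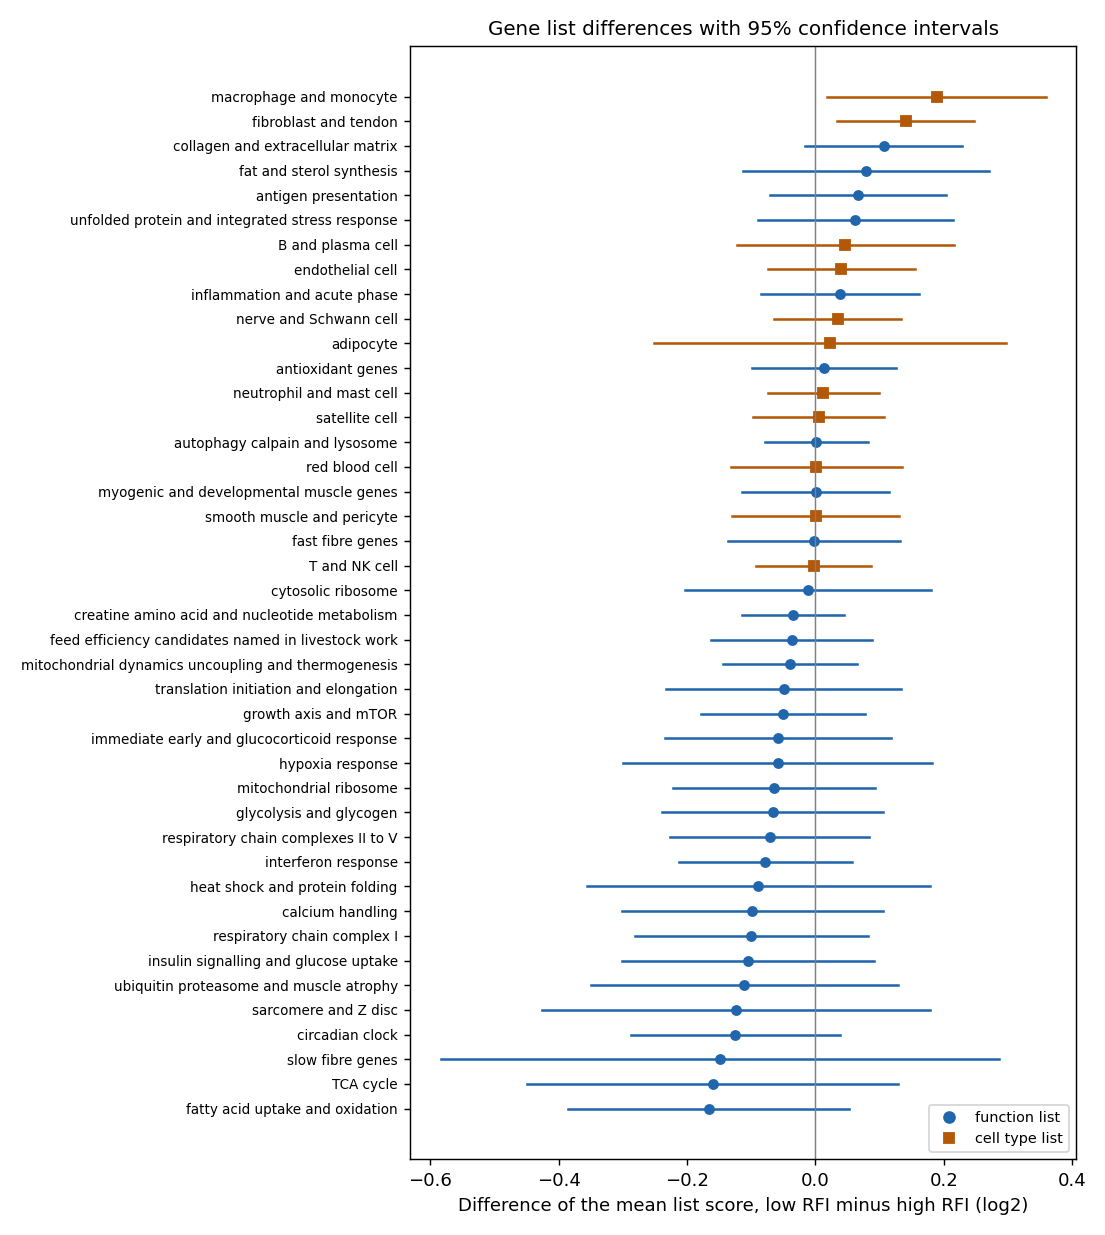
Difference of the mean score (horizontal axis, log2, low RFI minus high RFI) of the 42 gene lists, with points for the mean over 10 animals per group and lines for 95% confidence intervals; circles are function lists and squares are cell type lists. The intervals of the fibroblast and tendon list (0.033 to 0.25) and of the macrophage and monocyte list (0.018 to 0.36) lie above 0, before any adjustment for the number of lists, and the others include 0.

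**Figure D3:**
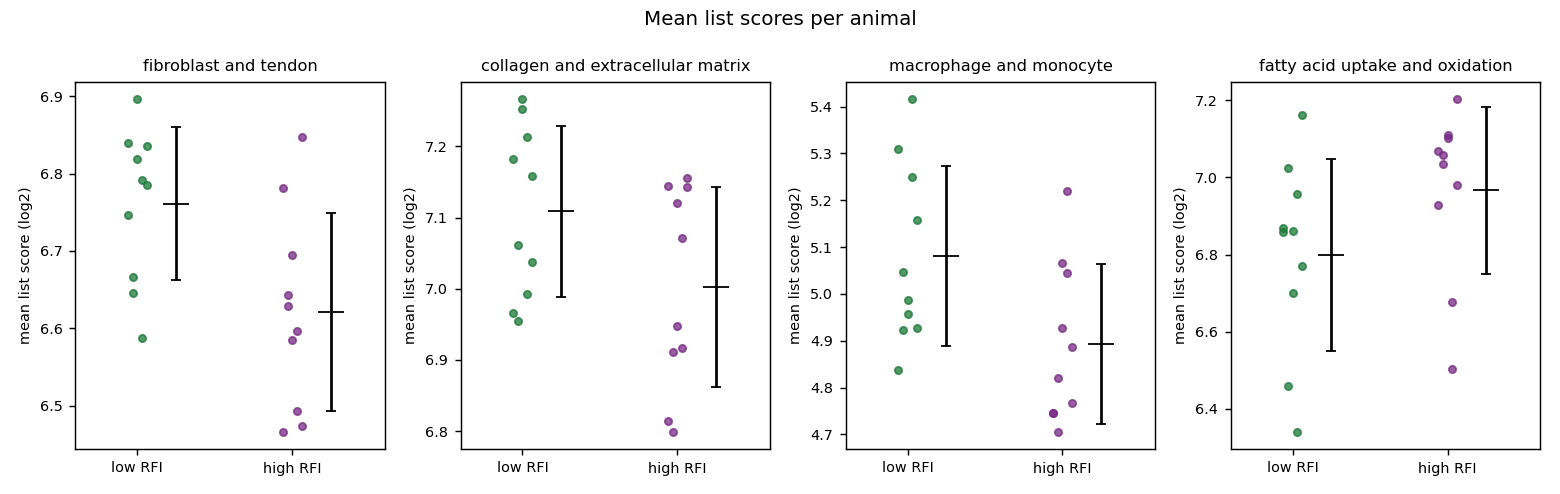
Mean score (vertical axis, log2) of 4 lists, with 1 point per animal and the mean ± SD of each group of 10. The groups overlap in each list; fibroblast and tendon scores span 6.59 to 6.90 in low RFI and 6.47 to 6.85 in high RFI.

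The largest source of variation between the arrays lay within both groups. Principal component 1 held 27.5% of the variance and followed the mean signal of the 23 antigenomic background control probe sets, which carry no pig sequence (Pearson r = 0.930, permutation p = 1e-05; Spearman rho = 0.890, permutation p = 1e-05, the smallest that 100000 permutations can give). Without the 2 arrays farthest from the median background r was 0.891, and within the groups it was 0.914 in low RFI and 0.966 in high RFI. Scores of the TCA cycle (r = -0.965 with component 1), sarcomere (r = -0.946), calcium handling (r = -0.910) and fatty acid oxidation lists (r = -0.903) ran against it, whereas the collagen (r = -0.084) and fibroblast lists (r = -0.191) did not follow it closely. With the background control signal as a covariate, 22 of the 24 lists with a negative difference shrank by over 1.5 times or turned in sign, against 6 of the 18 with a positive one. The groups did not differ detectably on this component (7.09 ± 34.1 against -7.09 ± 38.0, SD, n = 10 each, permutation p = 0.390) or in background control signal (3.68 ± 0.16 against 3.63 ± 0.13, permutation p = 0.437).

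**Figure D4:**
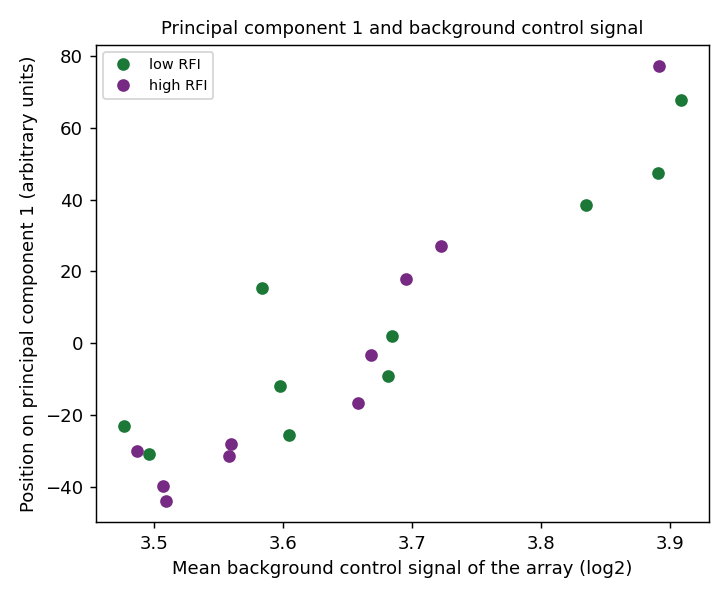
Position of each of the 20 arrays on principal component 1 (vertical axis, arbitrary units) against its mean background control signal (horizontal axis, log2), coloured by RFI group. The 4 arrays of highest background, low RFI replicates 7, 9 and 10 and high RFI replicate 9, lie at 3.83 to 3.91 and have the highest positions.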

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

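All tests weighed in this part were chosen after the results were seen, and the joint test of slopes, first of 5 lists and then of 10, replaced a test of the 2 most extreme slopes that had left the question open. In 458 groups of 10 values (list scores, named genes and array measures), 20 held an animal far from the others of its group by Dixon's ratio of gap to range, where chance gives about 1 in 20. High RFI replicate 9 accounted for 8 of them and low RFI replicate 9 for 4.

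High RFI replicate 9 had the lowest scores of its group for TCA cycle (7.44, next 7.89), cytosolic ribosome (6.70, next 7.14), mitochondrial ribosome (5.47, next 5.81) and calcium handling genes (7.81, next 8.17), and the lowest MYOZ2 (4.24, next 5.98). It had the highest nerve and Schwann cell score (4.88, next 4.68), MAL (3.18, next 2.63) and CYP11A1 (4.15, next 2.14). Low RFI replicate 9 had the highest T and NK cell score (4.41, next 4.24), TLR4 (6.05, next 5.49), LMOD1 (6.40, next 5.96) and LCK (4.78, next 4.39) of its group.

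The remaining values far from their group were spread over other animals. They were DFNB59 in low RFI replicate 2 (1.36, next 2.32), HIPK2 in high RFI replicate 10 (7.52, next 7.05), PSMB5 in low RFI replicate 1 (3.82, next 3.10; a mouse microRNA probe set that carries the symbol, not a measure of the PSMB5 transcript), RPS20 in low RFI replicate 3 (2.36, next 1.97) and MYH4 in low RFI replicate 10 (12.2, next 12.6). The others were SRL in high RFI replicate 5 (9.74, next 9.49), CD4 in high RFI replicate 6 (8.25, next 7.58) and MS4A1 in high RFI replicate 8 (2.29, next 1.84).

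Both replicates 9 lie at the end of principal component 1, where background control signal is high and muscle gene scores are low. RFI group held 4.12% of the variance of that component, which argues against the groups as its origin. Its correlation of 0.930 with the background control signal is consistent with a technical origin, such as a difference in RNA or hybridisation quality, though RNA quality itself was not measured here. A smaller share of muscle fibres in the piece cannot be told apart from this: after cyclic loess normalization the slopes of 10 non-muscle marker lists along the component gave p = 0.178 in a joint test of their equality (0.228 with 5 lists), with adipocyte minus endothelial at 0.085 in the first test (2 SE either way, -0.070 to 0.24). Only nerve markers rose by more than 2 SE (0.049 ± 0.021, SE, per SD of the component). Smooth muscle and pericyte markers fell (-0.072 ± 0.023), against a smaller share of fibres. Of these 10 genes 7 rose, among them DES, which is also in the sarcomere list. RGS5 (-0.88 ± 0.094) carried the fall of the mean, and ABCC9 (-0.33 ± 0.046) and KCNJ8 (-0.11 ± 0.044) also fell by more than 2 SE. An earlier rule would have excluded the explanation through this fall. The rule was then changed to ask also for a fall of the median member, and the explanation stays open only under the changed rule.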

How the results depend on the processing

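The settings using the background control signal, cyclic loess, the 4 arrays left out and the filter at 5 were chosen after the data were seen. Over 38 settings (limma at an adjusted p of 0.05, but for 1 with a rank test and 1 with a threshold of 0.10) the number of probe sets called stayed 0 in 35. The number of lists past an adjusted p of 0.05 in camera, fry or the permutation test stayed 0 in 36. The exceptions for probe sets were 1 with the first residual principal component as a covariate (an unnamed probe set, 10.7 ± 0.49 in low RFI and 9.84 ± 0.32 in high RFI, adjusted p 0.0409), 1 without the 4 arrays of highest background (CYP11A1, difference 1.53, adjusted p 0.00264), and 0 to 1 over the animals left out in turn, with the 1 being CYP11A1 without high RFI replicate 9 (adjusted p 0.00364). The residual component was taken from the group fit of these same values. It cannot change a group difference and only removes variation within groups, so p-values with it tend to be too small. The 4 arrays of highest background include high RFI replicate 9, so both CYP11A1 calls leave out that animal. With the background control signal as a covariate on all arrays 0 probe sets were called (smallest limma adjusted p 0.291). Over all settings CYP11A1 ranged from 0.73 to 1.74 and its smallest adjusted p was 0.00264. The unnamed probe set, singled out after its values were seen, had the smallest p of the table without the covariate (4.84e-05, limma adjusted p 0.941). For lists they were 10 with the preset correlation (4 to 16 over the settings) and 0 to 1 over the animals left out, the 1 being fibroblast and tendon without high RFI replicate 10 (adjusted p 0.0380, and 0.0380 to 0.554 over all settings with an estimated correlation). Lists kept their sign in every setting with camera for fibroblast and tendon (0.12 to 0.17), collagen (0.084 to 0.13), macrophage (0.11 to 0.22) and fatty acid oxidation (-0.22 to -0.099). The count at an unadjusted p under 0.05, 1306, became 2527 with the residual component as a covariate, 2025 without high RFI replicate 9, and 870, 429, 416 and 289 where fewer features were tested (filter at the median, 1 probe set per gene, mean of probe sets, filter at 5). Signs turned for 9 of 185 named genes and 21 lists, none called before or after the turn with an estimated correlation; the cause was not tested. With the filter at the median T and NK cell went to 0.00067. With median centring autophagy went to -0.0088, myogenic to -0.0098, smooth muscle to -0.0099, red blood cell to -0.0088 and satellite cell to -0.0055. With array weights PAX3 went to -0.024, fast fibre to 0.028, smooth muscle to -0.00019 and red blood cell to -0.025. With the label number block cytosolic ribosome went to 0.019, fast fibre to 0.020 and adipocyte to -0.0099. With the adipocyte covariate fast fibre went to 0.00026. With the mean of all probe sets EIF4G1 went to 0.029, MYH4 to 0.011, PDLIM7 to -0.0038, SLA-6 to -0.0061, GZMB to 0.25, CSF3R to 0.015, autophagy to -0.016 and neutrophil to -0.0095. With the background covariate MYH4 went to 0.015, cytosolic ribosome to 0.045, translation to 0.014, fast fibre to 0.035, hypoxia to 0.017 and red blood cell to -0.016. With cyclic loess cytosolic ribosome went to 0.0052, fast fibre to 0.035, neutrophil to -0.00073 and red blood cell to -0.0043. Without the 4 arrays of highest background MYH4 went to 0.017, MYH11 to -0.053, RGS5 to 0.025, PAX3 to -0.095, glycolysis to 0.013, cytosolic ribosome to 0.037, translation to 0.022, fast fibre to 0.057, hypoxia to 0.021, creatine metabolism to 0.0015, mitochondrial dynamics to 0.0063, feed efficiency candidates to 0.0037, T and NK cell to 0.0083, B and plasma cell to -0.016, red blood cell to -0.041 and satellite cell to -0.0044. With the filter at 5 autophagy went to -0.028, myogenic to -0.024, unfolded protein to -0.026, antioxidant to -0.0087, interferon to 0.012, inflammation to -0.0081 and smooth muscle to -0.012. Over the animals left out in turn autophagy ranged from -0.019 to 0.015, cytosolic ribosome from -0.067 to 0.038, fast fibre from -0.021 to 0.028, myogenic from -0.021 to 0.024, satellite cell from -0.012 to 0.020, smooth muscle from -0.032 to 0.027, T and NK cell from -0.025 to 0.015, red blood cell from -0.031 to 0.032, antioxidant from -0.0099 to 0.043, PAX3 from -0.019 to 0.084, adipocyte from -0.029 to 0.089, neutrophil from -0.0074 to 0.027 and MYH4 from -0.12 to 0.0081. No paired analysis was possible because the labels give no litter or batch by which animals could be paired. A pairing in the design therefore cannot be excluded. Probe sets near the background controls (means 1.03 to 7.84 by probe composition) carry little signal above it, which limits dim genes such as CYP11A1 and LIPM.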

Other observations

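Chosen after the results were seen were the relations between lists, the tests of background signal and of non-muscle markers for the connective tissue lists, and all comparisons with random splits but that of the fibroblast list. Some pairs of lists varied together between animals, and others not detectably. The adipocyte score followed that of fat and sterol synthesis (Pearson r = 0.768, permutation p = 9e-05; Spearman rho = 0.767, permutation p = 1.4e-04; adjusted p = 2.7e-04 over 6 relations), with r = 0.818 without the 2 animals farthest from the median and r = 0.838 in low RFI and 0.812 in high RFI. With the background control signal taken out r was 0.780 (adjusted p = 4.8e-04). The slow fibre score followed that of fatty acid oxidation (r = 0.786, permutation p = 7e-05; rho = 0.747, permutation p = 2.7e-04; adjusted p = 2.7e-04), with r = 0.696 without the 2 extremes, 0.854 in low RFI, 0.707 in high RFI and 0.743 with the background taken out.

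Immediate early and glucocorticoid response genes followed circadian clock genes (r = 0.681, permutation p = 9.4e-04; rho = 0.743, permutation p = 2.3e-04; adjusted p = 0.00188; PER1, shared by both lists, was left out) and heat shock genes (r = 0.635, permutation p = 0.0027; rho = 0.582, permutation p = 0.00815; adjusted p = 0.00405). Without the 2 extremes these were 0.587 and 0.506, within low RFI 0.676 and 0.672, within high RFI 0.678 and 0.584, and with the background taken out 0.637 and 0.574. Macrophage and collagen scores gave r = 0.369 (permutation p = 0.109; rho = 0.415, permutation p = 0.0704; adjusted p = 0.131; 0.197 without the 2 extremes, 0.363 in low RFI, 0.092 in high RFI, and 0.462 with the background taken out, adjusted p = 0.047). On that last scale rho was 0.382 (permutation p = 0.098). There r was 0.365 without the 2 extremes, 0.430 in low RFI and 0.241 in high RFI, so the relation is weakly held. Interferon and antigen presentation scores gave r = 0.036 (permutation p = 0.881; rho = 0.102, permutation p = 0.669; adjusted p = 0.881; -0.013 without the 2 extremes, 0.055 in low RFI, 0.152 in high RFI). With the background taken out this last r was 0.352 (permutation p = 0.128; 0.180 in low RFI, 0.642 in high RFI).

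The gene CYP11A1, picked for its small p in these same values, separated the groups in all animals but 1. Such a separation follows in part from the choice and adds no support, and over all animals its limma adjusted p was 0.998. In 9 of 10 high RFI animals it read at or below 2.14, and in 10 of 10 low RFI animals at or above 2.18, with high RFI replicate 9 at 4.15, among the low RFI values. Both group means lie below the mean background control signal of 3.65. The mean of both its probe sets differed by 0.73, so the other probe set showed almost no difference. The 3 highest readings (4.29, 4.15 and 4.07) came from arrays among the 4 of highest background. With the background control signal as a covariate the difference was 1.30, and without those 4 arrays 1.53.

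The higher connective tissue values in low RFI were weighed against 3 explanations. The tables argue against background signal as the origin: the fibroblast and tendon difference was 0.16 (95% interval 0.050 to 0.26) with the background covariate and 0.14 without. More non-muscle cells of every type stay open: fibroblast and tendon markers exceeded the mean of the 9 other non-muscle marker lists (difference 0.038) by 0.10 (95% interval -0.020 to 0.22), and a first comparison with 4 lists that left out macrophages gave 0.12 (95% interval 0.018 to 0.21). Chance could not be excluded, since 13 of 100 splits of the animals gave some list a camera p as small as the 0.00601 of the fibroblast list, the smallest of the other splits being 6.36e-05. Whether low RFI muscle may hold more connective tissue, or more matrix expression per cell, stays open.

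Camera with the preset correlation called 10 lists, but 26 of 100 splits called as many, with up to 19 in the others and a median of 5, so chance could not be excluded. The background control signal as a covariate was chosen after the data were examined, though the prediction for it was written before its result was seen. Adding it left 4 of the 10 called (fatty acid oxidation, collagen, fibroblast and macrophage). Of the other 6, complex I, TCA cycle, proteasome and calcium handling shrank most, for example TCA cycle from -0.16 ± 0.14 (SE) to -0.063 ± 0.065 and calcium handling from -0.098 ± 0.097 to -0.034 ± 0.056, which is consistent with background signal contributing to them. Circadian clock (-0.12 ± 0.078 to -0.077 ± 0.051) and interferon response (-0.078 ± 0.064 to -0.053 ± 0.058) shrank no more than fatty acid oxidation (-0.17 ± 0.10 to -0.10 ± 0.065), which kept its call, so their lost calls do not speak for background. With the same covariate and an estimated correlation camera called 0 lists (smallest adjusted p 0.207).

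With 0 probe sets called by limma and 0 lists by camera, 100 of 100 splits reach the real count in each case by construction, so the splits decide nothing there; the highest of the others were 1281 probe sets and 1 list. For the 1306 probe sets at an unadjusted p under 0.05, 51 of 100 splits gave as many, with up to 6853, so chance could not be excluded. The split with 6853 had its groups 44.1 apart on principal component 1, against 14.2 for the real groups, so the large counts point to that structure of the arrays.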
